A study of Komagataella phaffii GS115 with 12 samples.

How the data were processed

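Expression was measured on 12 NimbleGen arrays, 3 for each of 4 groups, in total RNA labelled with Cy3, and each group's 3 samples came from separate cultures per the labels. Per the series' design text, an array measures 5777 genes with 8 probes each. The deposited values are on the log2 scale, 1 value per row and array, and RMA is named in the submitters' processing notes. The version, the array design and the background correction are not given in the sources used here. The 28680 values hold 5378 distinct levels, of which 632 occur on every array, and all 12 arrays have the same highest value. Bright levels are far apart, with 0.18 between the 2 highest, so a bright row can show the same value on all replicates. The second-highest value of every row was at least 6.59, near the median of all values of 6.64. Whether rows were removed for low signal is not given in the sources used here. The table was used as deposited, with 2390 rows. No scanner files, detection flags, slides or scan dates were used here, so no row could be called above background, and the number of arrays limits the precision.

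Row names were matched to the K. phaffii RefSeq gene table (assembly ASM2700v1), where 0 of 2390 occurred, and to the S. cerevisiae SGD gene table that comes with the R package GenomicFeatures 1.54.1, where 2390 of 2390 occurred. Neither table pairs these names with symbols or products. The 31 gene lists that had been fixed for pathway tests, by product and symbol, could therefore not be matched to rows, and no list was tested. For the same reason the planned check of the rows for methionine adenosyltransferase and CYS4 was not made, and no coordinates are given. The rule for named rows then leaves the 2 largest rises and the 2 largest falls of each comparison, among rows past the threshold whose 3 values in 1 group all lie above the 3 in the other. Rows named outside this rule are said to be so.

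Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model of the 4 groups over all 12 arrays, with no replicate block, and p-values were adjusted by Benjamini-Hochberg over the 2390 rows of each comparison, with a threshold of 0.05. All tests were two-sided. SE is limma's moderated standard error of a difference and SD the spread of the 3 arrays of a group. The comparisons, the rule for names and the alternatives were fixed before the data were examined. The limit of 8 on a row's mean, the comparisons of the 24 h group with DS56 and with the control, and the overlaps other than that of the 2 strains against control were chosen after seeing the data. Chance agreement between comparisons that share arrays was taken from 100 simulations of unchanged groups with each group's own spread. Their noise was independent for each row and array. The simulated ranges therefore hold no correlation between genes and no effect common to the rows of an array.

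The model was tested on simulated data: 200 of 2390 rows were changed by 0.5, 1 or 2 on the log2 scale. For DS56 against control it recovered 55.2% of changes of 0.5 and 100% of those of 1 and 2, with 7.61% false calls. For G12-CBS against DS56 it recovered 64.2% of changes of 0.5 with 7.85% false calls, and for G12-CBS at 72 h against 24 h 58.2% with 3.37%. For G12-CBS against control it recovered 53.7% of changes of 0.5 and 98.5% of changes of 1, with 21.5% false calls. These 46 of 214 calls were above the limit first set for the self-test, which was then applied to the fit to the 6 arrays instead. The model had been fixed before the data were examined and was kept. A fit to the 6 arrays of that comparison recovered 28.4% of changes of 0.5 with 3.82% false calls. The alternatives were a replicate block, a fit to the 6 arrays compared, quantile normalization, centring on the median, removal of the dimmest 25% of rows, a variance trend with robust moderation, array weights, a test against a 1.2-fold change (treat) and leaving out each array. Figures were drawn with matplotlib 3.10.9.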

Results

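Total RNA from 12 samples of methanol-induced Komagataella phaffii GS115, the methylotrophic yeast also known as Pichia pastoris, was measured on 12 one-colour Cy3 arrays. The samples fell into 4 groups of 3, and the 3 of each group came from separate cultures. The control group was the strain GS115/3.5K, which held the empty vector pPIC3.5K, at 72 h of methanol induction. The second group was the strain GS115/DS56, called DS56 here, which carried DS56, a recombinant methionine adenosyltransferase gene, for the synthesis of S-adenosyl-L-methionine, also at 72 h. The third was the G12-CBS strain at 72 h, which carried the same gene and had its CYS4 gene placed under the weak promoter G12. CYS4 encodes cystathionine beta-synthase, the enzyme that draws homocysteine into the transsulfuration pathway. These 3 groups had been fed L-methionine at 24 h of induction. The last group was G12-CBS at 24 h of induction, sampled without L-methionine feeding. The phenotype labels class DS56 and G12-CBS at 72 h as high producers of S-adenosyl-L-methionine, and the control and G12-CBS at 24 h as low producers, while the sample titles class G12-CBS as a high-producing strain at both times.

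The table held 2390 rows, each named by 1 identifier, with values from 5.62 to 15.76 on the log2 scale. No row name occurred among the 5040 K. phaffii genes of the RefSeq table, and all 2390 occurred among the systematic open reading frame names of Saccharomyces cerevisiae. The files do not pair these names with gene symbols or products, so rows are reported by identifier. Which rows, if any, stand for CYS4 or the recombinant gene was therefore not determined here. How well the probes of a row match a K. phaffii transcript is not known here, so levels are compared only within a row. Whether the probes were designed for S. cerevisiae is not known here either. A difference in a row is therefore not shown to belong to a particular K. phaffii gene. Most rows lay low in the range: the mean over the 12 arrays was below 7 in 83% of them, and 160 rows had a mean of 8 or above. Array medians ran from 6.65 to 6.66 in DS56 and G12-CBS at 24 h, and from 6.59 to 6.62 in the control and G12-CBS at 72 h. Replicates of the DS56 strain and of G12-CBS at 24 h were closer together, with a median SD per row of 0.112 and 0.095 (n = 3 each), than those of the control strain and of G12-CBS at 72 h, with 0.185 and 0.177.

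The DS56 arrays and the G12-CBS 24 h arrays stood closest to each other of all pairs of groups. Their 9 pairs had Pearson correlations across rows of 0.977 to 0.983, against 0.983 to 0.985 within DS56 and 0.987 to 0.991 within G12-CBS 24 h. The control arrays correlated at 0.924 to 0.934 with the DS56 arrays and at 0.920 to 0.933 with the G12-CBS 72 h arrays. G12-CBS at 72 h and at 24 h, the same strain, correlated at 0.906 to 0.915. These are correlations across genes, which are not independent replicates.

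**Figure D1:**
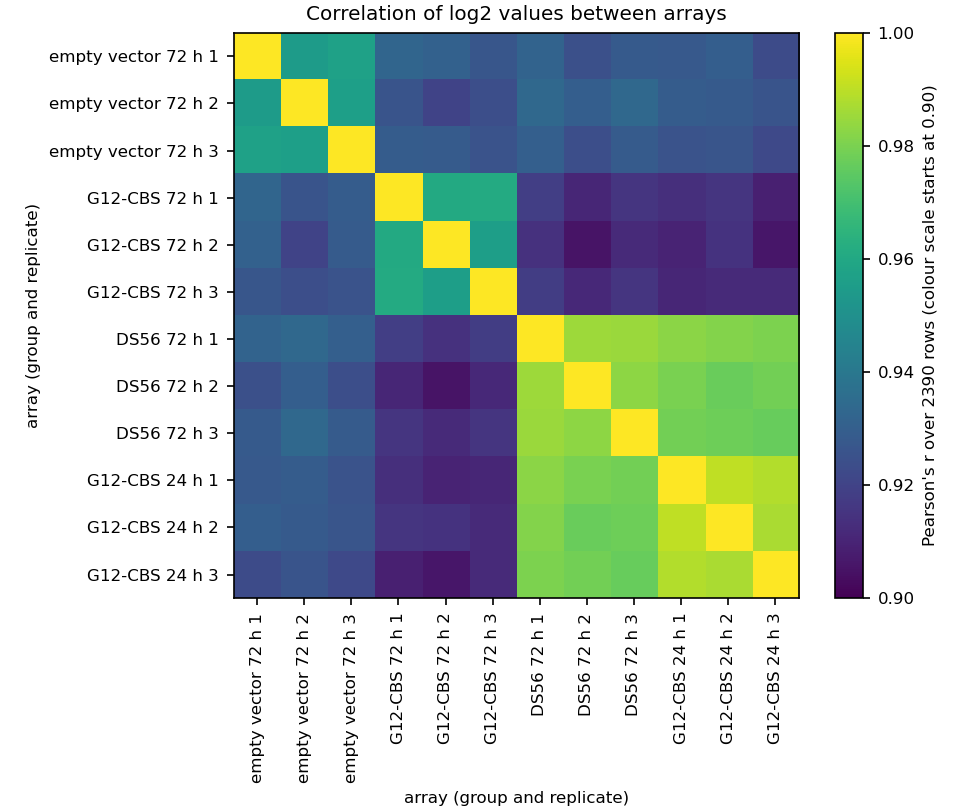
Pearson correlation of the log2 values between each pair of the 12 arrays, over 2390 rows, with arrays ordered by group and replicate on both axes and the colour scale starting at 0.90. The 6 arrays of DS56 at 72 h and G12-CBS at 24 h form a block at 0.977 and above, while the other pairs of groups lie between 0.905 and 0.934.

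The comparison of DS56 with the empty-vector strain at 72 h asked what the recombinant methionine adenosyltransferase gene changed under L-methionine feeding. YDR502C showed the largest difference in either direction: it rose from 10.47 ± 0.29 (SD, n = 3) in the control to 15.76 ± 0 (SD, n = 3), the highest level of the table, on all 3 DS56 arrays. That is a log2 difference of 5.29 ± 0.13 (SE), or 39.0-fold on the deposited values, with limma's adjusted p = 1.01e-16. A larger difference could not have shown on this scale. The top level is the same on all 12 arrays, whichever row holds it, so the true ratio may be larger or smaller. An SD of 0 at this level does not measure the spread of replicates, so the SE and p-value may be too small. YNL122C rose 4.46-fold, from 7.49 ± 0.31 to 9.65 ± 0.27 (adjusted p = 1.32e-07). YHR007C-A fell from 15.21 ± 0.10 to 12.57 ± 0.16, a log2 difference of -2.64 ± 0.13 (SE, adjusted p = 7.83e-12), and YOR072W-B fell from 12.34 ± 0.07 to 10.63 ± 0.08 (adjusted p = 5.10e-09). In all, 433 of 2390 rows passed an adjusted p of 0.05, of which 288 rose and 145 fell, and 39 of them changed at least 2-fold, 24 up and 15 down. Of the 160 rows with a mean of 8 or above, 55.0% passed, 43 rising and 45 falling, against 15.5% of the 2230 dimmer rows. The 3 arrays of each group did not overlap in 33.8% of rows, where chance gives 10%. Rises made up 66.5% of the calls on the deposited scale, but 53.5% after each array was centred on its median and 55.2% after quantile normalization. The count fell to between 239 and 253 when any 1 DS56 array was left out (253 without replicate 1, 239 without replicate 2 and 246 without replicate 3).

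G12-CBS was compared with DS56 at 72 h to see what placing CYS4 under the weak promoter added to the recombinant gene. Whether CYS4 expression was lowered was not checked. YNL190W was 10.9-fold higher in G12-CBS, at 10.52 ± 0.10 against 7.07 ± 0.20 (SD, n = 3 each). YKL138C was 9.38-fold higher, at 10.05 ± 0.16 against 6.82 ± 0.12 (limma's adjusted p = 2.99e-13 for both). The DS56 levels of both rows were not shown to lie above background, so these are folds of the measured values. YNL122C, which had risen in DS56, was lower in G12-CBS, at 7.20 ± 0.39, a log2 difference of -2.45 ± 0.19 (SE, adjusted p = 8.68e-09). YJL189W fell from 9.85 ± 0.04 to 7.49 ± 0.31, a log2 difference of -2.35 ± 0.14 (SE, adjusted p = 3.63e-10). YDR502C was at 15.76 on all 6 arrays of these strains, the top of the scale, so the 2 strains could not be ranked for it. The test passed 535 rows, 199 higher and 336 lower in G12-CBS, with at least 2-fold changes in 30 and 35 of them. Of the rows with a mean of 8 or above, 53.1% passed, and of the dimmer rows 20.2%. Lower rows outnumbered higher ones on the deposited scale, where 37.2% of calls were higher, and this share was 47.6% after centring on the median and 47.2% after quantile normalization. Leaving out DS56 replicate 2 lowered the count to 355.

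G12-CBS and the empty-vector strain at 72 h differed by both engineering steps. YDR502C again rose from 10.47 ± 0.29 to 15.76 ± 0 (SD, n = 3 each), the top of the scale. This was 39.0-fold on the deposited values, with the same limits as in DS56 (limma's adjusted p = 1.01e-16). YNL190W was 8.51-fold higher, at 10.52 ± 0.10 against 7.43 ± 0.15 (adjusted p = 1.02e-12). YJL189W showed the largest fall, from 10.73 ± 0.20 to 7.49 ± 0.31, 9.42-fold (adjusted p = 1.02e-12), and YBR162W-A fell 3.60-fold, from 9.94 ± 0.13 to 8.09 ± 0.16 (adjusted p = 4.40e-09). The model over all 12 arrays passed 220 rows, 120 higher and 100 lower, and 29 of them changed at least 2-fold, 23 up and 6 down. Both groups here had the larger spread between replicates. In data simulated with each group's own spread, this model gave 21.5% false calls in this comparison, 46 of 214. The simulation changed 67 rows by 1 and 66 by 2 on the log2 scale, against 29 real calls of at least 2-fold. With fewer large changes, the same number of false calls is a larger share. The share among the 220 rows is therefore not known and may be higher than 21.5%. With the spread taken from the 6 arrays compared, 51 rows passed, 34 higher and 17 lower, all among the 220, and 97 passed with array weights. The simulated share of false calls was 3.82% with the 6 arrays, and it rests on the same simulated changes.

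The last comparison followed G12-CBS from 24 h of methanol, before L-methionine was fed, to 72 h, after feeding. Time on methanol and L-methionine feeding differed together and cannot be told apart. YKL138C rose 9.71-fold between 24 h and 72 h, from 6.77 ± 0.11 to 10.05 ± 0.16 (SD, n = 3 each, limma's adjusted p = 3.38e-13). Its 24 h level lay near the median of all values, 6.64, and was not shown to lie above background. YNL190W rose 9.50-fold, from 7.27 ± 0.18 to 10.52 ± 0.10 (adjusted p = 4.81e-13). YNL122C fell from 9.80 ± 0.15 to 7.20 ± 0.39, 6.05-fold (adjusted p = 2.33e-09), and YHR021C fell from 11.11 ± 0.05 to 8.67 ± 0.45, 5.42-fold (adjusted p = 1.14e-09). YDR502C was already at 15.70 ± 0.10 at 24 h. Of 2390 rows, 546 passed the test, 197 higher and 349 lower at 72 h, with at least 2-fold changes in 31 and 37 of them. Among rows with a mean of 8 or above, 58.1% passed, 45 higher and 48 lower, and among dimmer rows 20.3%. The share of higher rows among the calls was 36.1% as deposited, 46.5% after centring on the median and 48.2% after quantile normalization.

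**Figure D2:**
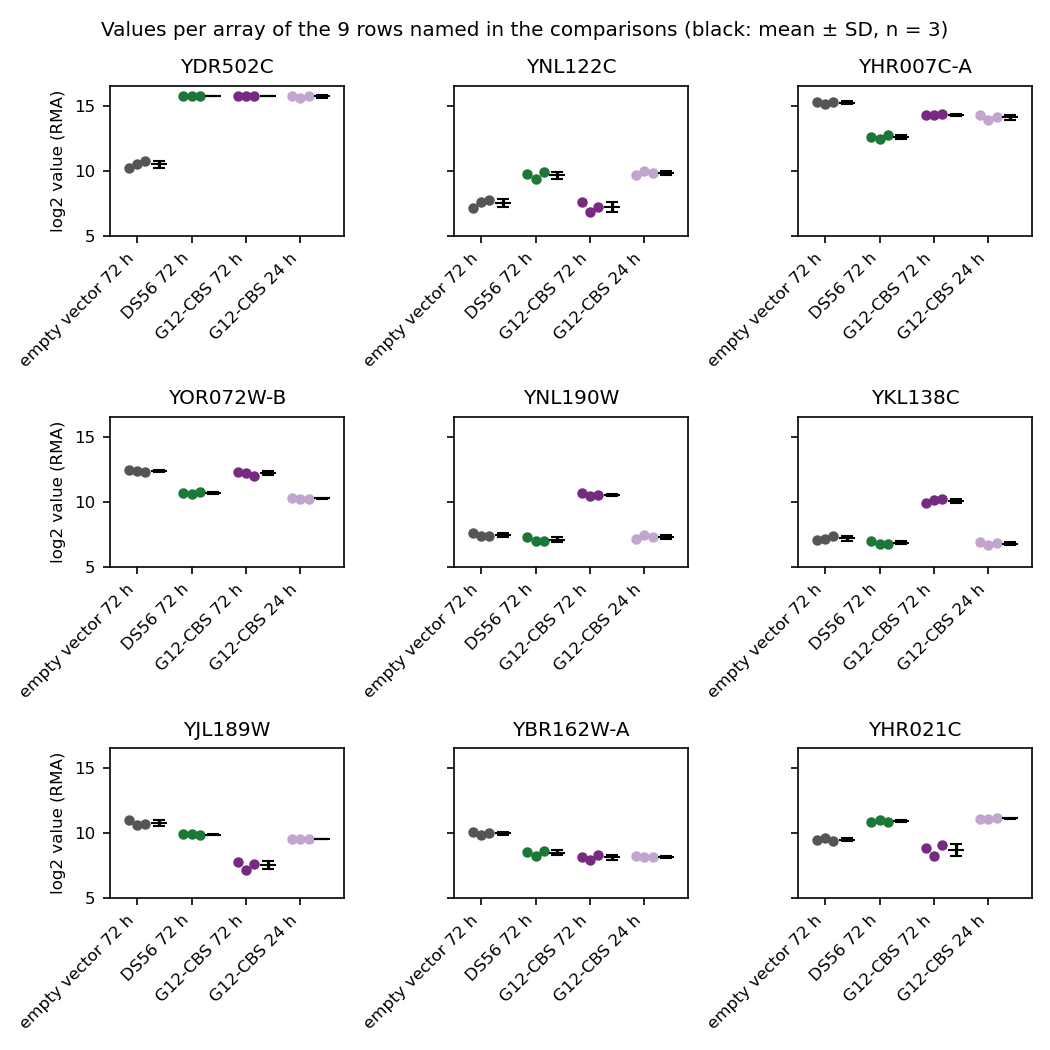
Log2 values per array (vertical axis, RMA scale, not starting at 0) of the 9 rows named in the 4 comparisons, by group, with the mean and SD of the 3 arrays in black. YDR502C lies at 15.76 on all DS56 and G12-CBS 72 h arrays against 10.47 in the control, and YNL190W and YKL138C lie at means of 10.52 and 10.05 in G12-CBS at 72 h against 7.43 and below in the other groups.

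The DS56 and G12-CBS strains at 72 h were set side by side against their shared control arrays. In both strains 17 rows rose, YDR502C among them, and 30 rows fell. YBR162W-A was among those that fell, with a log2 difference from control of -1.50 ± 0.13 (SE) in DS56 and -1.85 ± 0.13 in G12-CBS. Lists of these sizes drawn independently would share 14.5 rising and 6.1 falling rows, against 17 and 30 observed. Such expectations treat all rows alike, although rows with a mean of 8 or above were called more often in both comparisons. The shares were 55.0% against 15.5% of dimmer rows for DS56, and 27.5% against 7.9% for G12-CBS. Unchanged groups simulated against the same control arrays shared 0.15 rows on average and at most 2, which covers chance calls in the absence of any effect and is no measure of agreement between lists of real changes. A further 15 rows passed in both comparisons in opposite directions: 10 rose in DS56 and fell in G12-CBS, where independent lists would give 12.1, and 5 did the reverse, against 7.3. Log2 differences of the 2 strains correlated across rows at 0.30, below the 0.62 that unchanged groups gave through the shared control arrays. The central 95% of 100 simulations ran from 0.59 to 0.65, which may be too narrow, since simulated rows were independent. The covariance of the 2 strains' differences was 0.0353, against 0.0184 simulated. YDR502C, at 5.29 in both strains, adds to this excess and may make up much of it, and its share was not computed. The excess therefore does not show a response shared across the table. The 3 control arrays could not be split into parts of at least 2, so part of the excess may come from them. The 47 rows changed alike became 13 with the spread taken from the 6 arrays of each comparison, 26 with array weights and 29 without DS56 replicate 1.

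Of the 535 rows in which G12-CBS at 72 h differed from DS56 and the 546 in which it differed from its own 24 h cultures, 396 were called in both comparisons, which share the G12-CBS 72 h arrays. These were 139 higher in both, 256 lower in both and 1 in opposite directions. Independent lists, with bright and dim rows treated alike, would share 16.4 higher and 49.1 lower rows. Simulated unchanged groups, which hold no effect and so measure only chance calls, shared at most 1 row. The differences of the 2 comparisons correlated across rows at 0.92, against 0.76 simulated, with a covariance of 0.158 against 0.0171. YNL190W and YKL138C led the rises in both and YNL122C the falls.

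The differences of DS56 from control and of G12-CBS at 24 h from 72 h share no array and no strain. Across the 2390 rows they nevertheless correlated at 0.55 (0.52 to 0.55 when any 1 array was left out), where simulated unchanged groups gave 0 (-0.04 to 0.04). The simulated rows were independent, so this range may be too narrow for rows that move together. The correlation was 0.56 in the 1984 rows with a mean below 7 and 0.52 in the 160 rows with a mean of 8 or above. Of the rows called in both, 175 rose in DS56 and were lower in G12-CBS at 72 h than at 24 h. Independent lists, with bright and dim rows treated alike, would give 42.1. Another 47 fell in DS56 and were higher at 72 h, against 12. YNL122C was of the first kind. The other pairing of the groups, DS56 minus G12-CBS 24 h against control minus G12-CBS 72 h, correlated at 0.02. Of the 4 comparisons, that of G12-CBS with the control at 72 h is the only one that does not set a group of the closer-spaced arrays against a group of the wider-spaced ones. No slide or scan date was used here, so in the other 3 comparisons an array batch that followed this division could not be told apart from the groups.

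**Figure D3:**
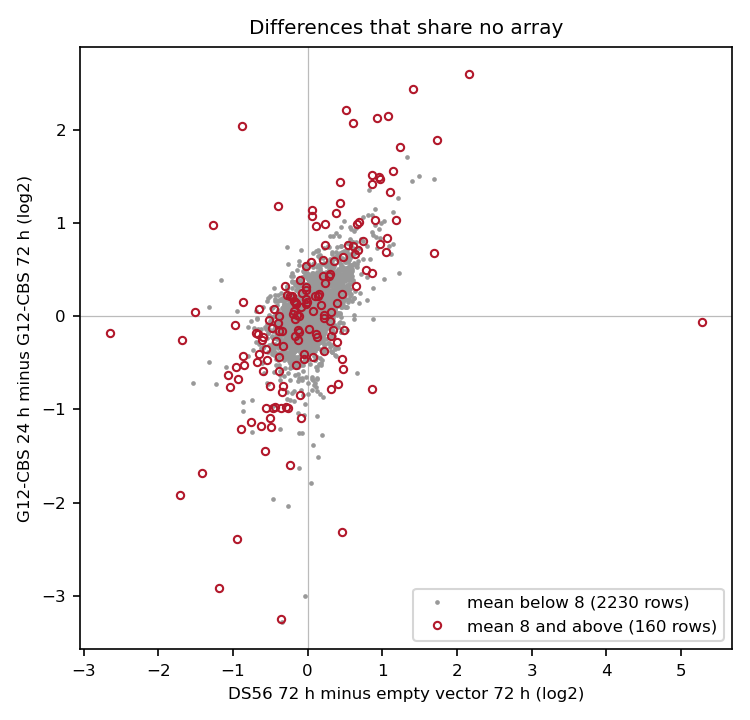
Log2 difference of DS56 from the empty-vector strain at 72 h (horizontal axis) against that of G12-CBS at 24 h from 72 h (vertical axis), 1 point per row, with the 160 rows of mean 8 and above as open circles and the 2230 dimmer rows as dots. The cloud rises from lower left to upper right (r = 0.55), and YDR502C stands alone at 5.29 on the horizontal axis.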

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

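The 16 values of named rows kept their direction and passed the threshold in all 224 alternative fits, with adjusted p-values up to 0.000249 with limma. These rows had been picked from the same arrays as the largest called changes, so this outcome was likely beforehand and says little about the other calls. The comparison of G12-CBS at 24 h with DS56 was chosen after seeing the data. Against a 1.2-fold change, 87 rows passed for DS56 against control, 160 for G12-CBS against DS56, 53 for G12-CBS against control and 160 for G12-CBS at 72 h against 24 h, and 11 for G12-CBS at 24 h against DS56, since this test asks for more than a difference from 0. With only the 6 arrays compared, G12-CBS against control kept 51 of its 220 rows, the comparison of G12-CBS at 24 h with DS56 rose from 23 to 66, and the rows changed alike in both strains fell from 47 to 13. Array weights gave 97, 76 and 26 for these, and the cause was not tested. Leaving out 1 array gave 239 to 390 rows for DS56 against control, 355 to 514 for G12-CBS against DS56, 164 to 243 for G12-CBS against control, 369 to 523 for G12-CBS at 72 h against 24 h, 15 to 20 for G12-CBS at 24 h against DS56 and 29 to 62 for the rows changed alike. The replicate block gave 395, 534, 216 and 539 rows in the 4 comparisons, 20 for G12-CBS at 24 h against DS56 and 44 for the rows changed alike. The numbers were not taken to pair the cultures: same-numbered arrays' deviations correlated at -0.12 to 0.18, above 0.1 in 2 of 18 pairs, and 6 of 12 arrays correlated best with their own number. Between G12-CBS at 72 h and 24 h the same-numbered pairs had 0.07, 0.12 and 0.18 and the others -0.14 to 0.02, and each of these 6 arrays correlated best with its own number there, a hint of pairing from the data and not from the design. The remaining alternatives left the counts of these 5 comparisons and of the rows changed alike within 1.5 times the reported ones, and the other overlaps were not run under them. The tests of the 31 gene lists and of the engineered genes were not run, since rows could not be matched. With 10 splits of 6 arrays, a share under 0.05 cannot be reached. The real split, 1 of the 10 to give as many rows, gave 433, 535, 220 and 546 in the 4 comparisons, and the highest other split gave 0, 0, 8 and 0.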

Other observations

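All tests of explanations here were chosen after the results were seen, and so was every row named outside the 4 comparisons. G12-CBS at 24 h and DS56 at 72 h, which differ in strain, time and feeding, differed in 23 rows by limma's test (adjusted p under 0.05, 138 at an unadjusted p under 0.05), 13 higher and 10 lower at 24 h. The count was 66 with the spread taken from these 6 arrays alone, 76 with array weights and 15 without G12-CBS 24 h replicate 2. YHR007C-A was higher at 24 h, at 14.08 ± 0.16 against 12.57 ± 0.16 (SD, n = 3 each, adjusted p = 1.89e-07), as was YLR466C-B, at 12.06 ± 0.18 against 10.96 ± 0.09 (adjusted p = 3.70e-05). YPR102C was lower, at 10.90 ± 0.09 against 12.34 ± 0.13 (adjusted p = 1.89e-07), and YOR063W was at 11.18 ± 0.10 against 12.22 ± 0.06 (adjusted p = 2.11e-05). YPR102C stood at 13.53 ± 0.10 in the control and 13.83 ± 0 in G12-CBS at 72 h.

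G12-CBS at 72 h stood apart from all 3 other groups in 67 rows that were higher and 41 that were lower against each of them, and 16 and 2 of these changed at least 2-fold throughout. With the spread taken from the 6 arrays of each comparison, an alternative chosen after seeing the data, 30 of the higher and 9 of the lower rows were called, and the rows of at least 2-fold again numbered 16 and 2. Its 3 arrays lay above the other 9 in 102 rows and below them in 105, where chance gives 10.9 of each. The 9 arrays of the engineered strains lay above the 3 control arrays in 47 rows and below them in 74. Only YDR502C, with a gap of 4.82, and YBR162W-A, with a gap of 1.2 the other way, did so by more than 1 on the log2 scale. The next gap above was 0.50, in YLR180W.

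YDR502C lay at or near the top of the scale in every engineered group, and the lowest of the 9 engineered arrays lay 4.82 above the highest control array. The control was fed and sampled at 72 h like DS56 and G12-CBS at 72 h, so feeding or late culture alone could not separate these groups. The unfed G12-CBS cultures of 24 h stood 5.23 ± 0.13 (log2, SE) above the control. In G12-CBS the high level thus came without feeding or late culture. A response to either was not tested, since no unfed 24 h control was measured. A difference in array processing between the closer and the wider groups is argued against by G12-CBS at 72 h. This group was 5.29 ± 0.13 (log2, SE) above the control, both groups being of the wider kind. Probes that read the introduced methionine adenosyltransferase transcript are a candidate explanation. It stays open, as does a change in a host transcript of the 2 strains. The gap of 4.82 is the observation itself and tests neither. Neither the probe sequences nor that of the recombinant gene were used here, and the S. cerevisiae gene behind the name YDR502C was not looked up.

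The arrays of DS56 at 72 h and G12-CBS at 24 h resembled each other although they differ in strain, time and feeding. The 2 groups differed in 23 rows, where no other split of the 6 arrays called any, so the 2 sets of arrays were not interchangeable. This cannot decide on a wrong label, with the 24 h arrays holding DS56 cultures of 72 h. Any difference between the 2 sets, such as separate cultures, could give such calls. A filter on dim rows is argued against as the cause by the correlation of 0.52 between the 2 independent differences in rows with a mean of 8 or above. A processing batch shared by these 2 groups, and another by the other 2, may account for the resemblance. The correlation was 0.56 in the 1984 rows with a mean below 7 (0.52 to 0.56 without any 1 array). These rows are most of the table in which the resemblance was first seen. The spread between replicates and the array medians divide the groups in the same way, so such a batch was not excluded. A shared state of the cultures cannot be told apart from this: limma called 0 of the 2230 rows below a mean of 8 between the 2 groups (82 at an unadjusted p under 0.05), but 24 with the spread of these 6 arrays alone and 31 with array weights, and no measure here says which of them hold signal.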
